A study of Mus musculus with 6 samples.

How the data were processed

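The 6 RNA libraries are from induced regulatory T cells, 3 with full-length FOXP3 (FL) and 3 with FOXP3 lacking exon 2 (dE2). Naive CD4 T cells had been stimulated over 3 days in the presence of TGF-beta at 5 ng/ml and IL-2 at 20 ng/ml, with plate-bound anti-CD3 and with anti-CD28, each at 1 µg/ml, per the labels' protocols. Polyadenylated RNA and the libraries were made by a sequencing company, per the labels' protocols. The submitters' processing notes name bcl2fastq, STAR 2.5, featureCounts of Subread 1.5.1, edgeR 3.20.8 and the genome build mm10, without their settings.

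The authors deposited a raw count per gene and library for 14777 genes, with the gene's identifier, exon coordinates and length, per the file headers. The rule by which the authors chose these genes is not given in the sources used here. The authors also deposited log2 CPM values, which equal edgeR's cpm with a prior count of 0.25 and no TMM factor, and were not used for tests. The deposited log2 fold changes and p-values of the authors' own comparison equal those of an edgeR likelihood ratio test on all 14777 genes with TMM and dispersions without the robust setting (largest difference in log10 p 1.6e-09). The authors' enrichment sheets give a p-value and a ratio (fold enrichment) per term, and their mapping table gives reads and percentages per library. The enrichment tool is not given in the sources used here. In the mapping table sense and antisense coding reads are about equal, with 48.4% to 49.8% sense, so the reads carry no strand information and antisense overlaps cannot be resolved.

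Samples were grouped by the genotype in the labels. All tests started from the deposited counts, in R 4.3.3. Genes were kept with edgeR's filterByExpr (14632 of 14777, 145 left out), scaled with TMM and tested with edgeR 4.0.16 (estimateDisp and glmQLFit with robust settings, glmQLFTest, group as the only term, two-sided). P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05, and fold changes are dE2 minus FL. The SE of a log2 fold change was taken as its size over the square root of the F statistic. CPM values are scaled with TMM and given as mean ± SD of 3 libraries. An exact permutation test of 3 against 3 cannot give a p under 0.1, so none was used. The biological coefficient of variation was 13.1%.

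Replicate numbers are shared between the groups. In log2 CPM deviations from the group means across genes, libraries with the same number correlated at 0.39, 0.21 and 0.19, and those with different numbers at -0.29 to 0.097. By a rule of each pair over 0.1 the numbers were taken to pair the libraries. The pairing is an inference from these same few libraries, since the labels do not say what a number shares, and the main fit does not use it. The fit with the number as a replicate block lowered the coefficient of variation to 9.2%. It has 2 residual degrees of freedom and a median of 291 prior ones, so its p-values lean on the trend of dispersion over all genes. On simulated unchanged genes, dE2 against FL, 4.73% of 14632 genes had p under 0.05 with the block and 4.91% without, and 0 were called in 5 draws. These draws used the trended dispersion and no effect of the replicate number. They therefore cannot show whether the block's p-values hold for genes whose dispersion departs from that trend.

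The 26 gene lists were fixed before the data were examined, from textbook markers of T cell fates, culture signals, metabolism, RNA quality and other cell types. They were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01), with camera at an estimated correlation, and with fry, adjusted over the lists. None of the camera calls held with an estimated correlation. That form takes its p from the residual degrees of freedom (4, or 2 with the block), so with few libraries it has little power. The Treg signature had an estimated correlation of -0.010, under the preset, yet its unadjusted camera p went from 0.0018 to 0.023. A failure there thus need not mean that correlation between genes made a list result. Some lists share genes, such as 4 genes between the co-inhibitory and follicular helper lists and 4 between the co-inhibitory list and the Treg signature. Genes named in the text are Foxp3, the 10 higher and 10 lower genes with the largest fold change (adjusted p under 0.05, mean CPM of at least 5, groups that do not overlap, no predicted models or receptor segments), 12 T cell genes fixed beforehand, and up to 4 members of each list with the smallest p. Of these genes 2, and of the 4 gene families tested afterwards 1, are not reported here. Others are said to be chosen after their values were seen.

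The alternatives were the replicate block, DESeq2 size factors, no composition factor, upper quartile scaling, DESeq2 1.42.0, limma-voom, the likelihood ratio test, no filter, CPM of at least 5 in 3 libraries, adjusted p under 0.01, glmTreat against 1.5-fold, each library left out, and a loess trend (span 0.5) of GC content or exon length removed from each library, with and without the block. GC content came from a GENCODE annotation of the same build for 14751 of the 14777 genes. The fit was tested on simulated data for dE2 against FL with 200 changed among 14632 genes, of which 14507 passed the filter, with some changed genes left out. In 1 draw it recovered 37.5% of genes raised and 34.2% of genes lowered 1.5-fold, 75% and 74.3% at 2-fold, and 100% raised 4-fold. Over 10 draws false calls averaged 10.6% with each gene's own dispersion and 4.49% with the trended dispersion. No 2 libraries of a group agreed within sampling noise (chi-square per gene of at least 9.11), so each counted as 1.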

Results

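The series profiled polyadenylated RNA from regulatory T cells (Treg) that were induced in culture from naive CD4 T cells of C57BL/6 mice. One group carried full-length FOXP3 (FL, 3 libraries) and the other carried the FOXP3 form that lacks exon 2 (dE2, 3 libraries). FOXP3 is the transcription factor that defines the Treg lineage. Both groups had been stimulated for 3 days with anti-CD3 and anti-CD28, TGF-beta and IL-2, and per the labels over 90% of cells were FOXP3 positive. The deposited count table held 14777 genes, with total counts of 13307155 to 16140432 per library, from 21827629 to 26231220 raw reads. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which can be technical. Pearson correlations of log2 CPM across genes were 0.985 to 0.991 within a group and 0.976 to 0.987 between groups. The first principal component held 41.7% of the variance and separated FL from dE2. In the authors' mapping table, 75.4% and 75.5% of high-quality mapped reads were assigned to genes in dE2 replicates 1 and 2, against 69.3% in dE2 replicate 3 and 69.3% to 71.5% in the FL libraries.

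The comparison addresses which genes differ in RNA level between cells with the FL and the dE2 form of FOXP3. It cannot tell genes that FOXP3 regulates directly from secondary changes. Foxp3 itself (ENSMUSG00000039521, mm10 chromosome X, 7579676 to 7595243, plus strand) did not differ between the groups in the test. Its CPM was 447, 397 and 337 in FL replicates 1 to 3 and 436, 403 and 335 in dE2 replicates 1 to 3, a log2 fold change of -0.01 ± 0.14 (SE; edgeR quasi-likelihood test, adjusted p = 0.985). The second coding exon lies at 7587074 to 7587178 and holds 105 bases, 2.63% of the gene's 3989 counted bases. The gene-level count covers all exons, so it checks the amount of Foxp3 RNA and not the loss of exon 2. Il2ra, the high-affinity IL-2 receptor chain of Treg, stood at 5154 ± 289 CPM in FL and 5325 ± 776 in dE2 (SD, n = 3; adjusted p = 0.895). Ctla4, an inhibitory receptor used by Treg, stood at 550 ± 79.4 and 522 ± 119.5 CPM (adjusted p = 0.836). The differences of the lineage regulator Ikzf2 (log2 fold change -0.38 ± 0.18, adjusted p = 0.235) and of Tnfrsf18 (0.27 ± 0.14, adjusted p = 0.263) did not pass the test. With the replicate block both passed, at adjusted p = 0.0014 for Ikzf2 and 0.034 for Tnfrsf18, and Ikzf2 also passed without dE2 replicate 1 (-0.55, adjusted p = 0.047).

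Of the 10 higher genes named by fold change, 5 encode cytokines, chemokines or a granzyme (Ifng, Il24, Ccl20, Cxcl10 and Gzmb). Ifng, the cytokine of type 1 T helper cells (chromosome 10, 118441046 to 118445892), rose from 214 ± 44.1 to 1085 ± 124.4 CPM (SD, n = 3; log2 fold change 2.34 ± 0.16 SE, adjusted p = 1.6e-08). Ly6c2, a surface protein of activated and memory T cells (chromosome 15, 75108158 to 75111970), rose by 2.54 ± 0.16, and Susd3 (chromosome 13, 49230690 to 49248706) by 1.80 ± 0.12. The cytokine gene Il24 rose by 2.21 ± 0.23, the chemokine genes Ccl20 and Cxcl10 by 1.78 ± 0.19 and 1.83 ± 0.22, and the interleukin 1 decoy receptor gene Il1r2 by 1.75 ± 0.21. Lilr4b and Cercam rose by 2.01 ± 0.23 and 1.60 ± 0.18. Adjusted p lay between 1.3e-08 and 1.7e-04 for these genes. Gzmb, the protease of cytotoxic granules, rose from 651 ± 249 to 2111 ± 171 CPM (1.70 ± 0.29, adjusted p = 0.017). The Gzmb call was lost when any single dE2 library was left out, at adjusted p = 0.052, 0.11 and 0.070 without replicates 1, 2 and 3. Its log2 fold change was 1.75, 1.63 and 1.69 in those fits. A fit without 1 library has less power, so a lost call need not mean a smaller difference. Ly6c2 and Lilr4b have near-identical neighbours (Ly6c1, Lilrb4a), so the split of reads between copies is uncertain.

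On the other side, Muc13, a membrane mucin, fell from 16.3 ± 6.48 to 2.66 ± 0.57 CPM (log2 fold change -2.62 ± 0.34, adjusted p = 0.0027). Sgk1, a serum and glucocorticoid regulated kinase, fell from 327 ± 32.4 to 154 ± 25.3 CPM (-1.09 ± 0.14, adjusted p = 5.0e-05). Carboxypeptidase E (Cpe, -1.63 ± 0.20), Prok1 (-1.33 ± 0.19), Epsti1 (-1.18 ± 0.17) and Slamf9 (-1.15 ± 0.20) fell with adjusted p between 4.6e-05 and 0.0017. Abi3bp (-1.39 ± 0.25), the sodium pump subunit Atp1b1 (-1.19 ± 0.22) and the interferon-induced GTPase Gbp2b (-1.43 ± 0.28) fell with adjusted p of 0.0082, 0.018 and 0.039. Gata3, the regulator of type 2 T helper cells, fell by 0.67 ± 0.13 on the log2 scale (adjusted p = 0.0038). Leaving out dE2 replicate 2 ended the calls of Muc13 (adjusted p = 0.055), Abi3bp (0.069), Atp1b1 (0.092) and Gbp2b (0.051), and leaving out dE2 replicate 3 ended those of Abi3bp (0.063) and Atp1b1 (0.086). The Gbp2b call was also lost without FL replicate 1 (0.13), FL replicate 2 (0.073), FL replicate 3 (0.093) or dE2 replicate 1 (0.071), and its reads can be shared with the copy Gbp2. Reads carried no strand information, so Atp1b1 cannot be told from the antisense gene Nme7 where they overlap. The same limit holds for Tnfrsf18 (Gm16008), Tnfrsf9 (Camta1), Il6ra (Gm42809), Xcl1 (Gm20743), Ccna2 (Exosc9) and Cyp51 (Akap9).

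**Figure D1:**
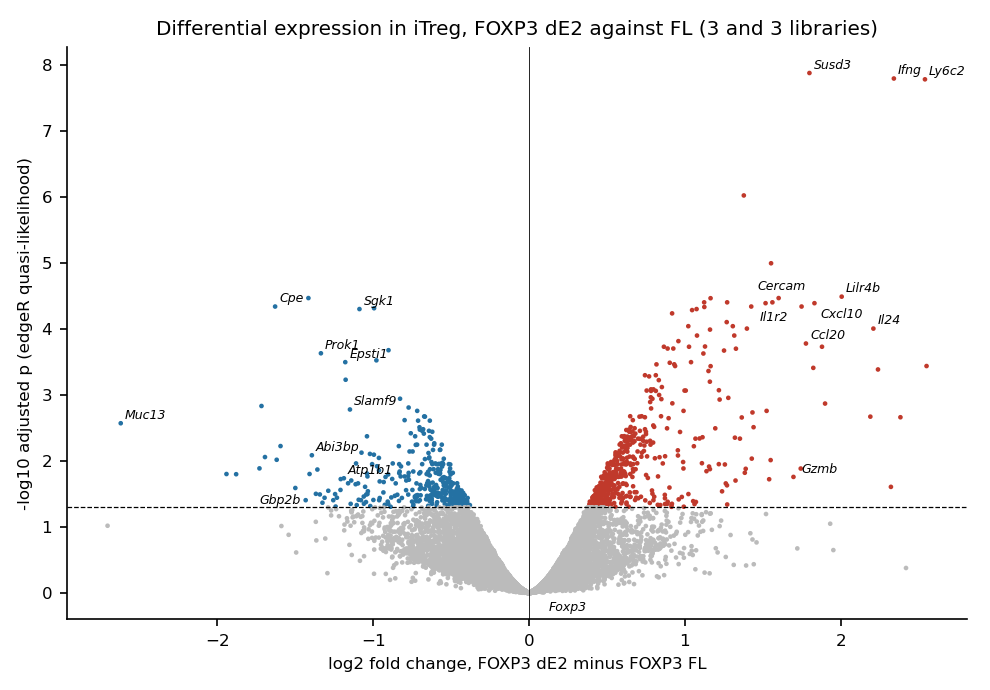
Log2 fold change of each tested gene (dE2 minus FL, horizontal axis) against -log10 of the edgeR adjusted p (vertical axis), 3 libraries per group. Red points are the 548 genes higher in dE2, blue points the 355 lower, grey points those that did not pass, the dashed line is an adjusted p of 0.05, and Foxp3 lies at a log2 fold change of -0.01.

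In all, 548 genes were higher and 355 lower in dE2 of 14632 tested (edgeR quasi-likelihood test, adjusted p under 0.05), which is 6.17% of the tested genes. By at least 2-fold, 81 were higher and 55 lower. On simulated data false calls of this test averaged 10.6% with each gene's own dispersion, above the threshold of 0.05, and 4.49% with the trended dispersion. In 27.1% of all tested genes the 3 libraries of one group lay wholly above those of the other, against 10% by chance. Replicate numbers were taken to pair the libraries, a pairing inferred from the same data. With this replicate block 1678 genes were higher and 1471 lower, and 99 were lower by at least 2-fold. All 548 and 355 genes were among those. The fold changes are relative to a composition factor (TMM). Without it, the median gene had a log2 fold change of -0.14 and the split became 264 higher and 954 lower, so that 21.7% in place of 60.7% of the calls were higher. Single libraries also moved the counts. Without dE2 replicate 2, 125 higher and 51 lower genes were called, 122 and 49 of them also with all libraries. The calls numbered 249 and 105 without FL replicate 1 (229 and 101 shared), 266 and 188 without FL replicate 2 (244 and 161), 360 and 166 without FL replicate 3 (338 and 157), and 780 and 587 without dE2 replicate 1 (503 and 294). At least 2-fold lower genes numbered 13 without dE2 replicate 2, 34 without FL replicate 1 or FL replicate 3, and 99 without dE2 replicate 1.

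Of 17 tested genes of the co-inhibitory list, 10 rose, 0 fell and 7 did not pass in dE2 (12 and 0 adjusted over the list alone). The list holds receptors that restrain T cells, and also ligand genes (Cd200, Cd274 and Pdcd1lg2), the ectoenzyme gene Entpd1 and the transcription factor gene Tox. The members included Cd160 (log2 fold change 1.38 ± 0.12, 45.6 to 118 CPM), Cd200 (1.33 ± 0.16), Havcr2, which encodes TIM-3 (1.15 ± 0.18), and Pdcd1, which encodes PD-1 (0.96 ± 0.13). The list's median log2 fold change was 0.66 (camera, adjusted p = 2.1e-08 over 26 lists; adjusted p = 0.239 with an estimated correlation). Of 17 type 1 T helper genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone). Beside Ifng these included the chemokine genes Ccl3 (1.52 ± 0.17) and Ccl4 (1.16 ± 0.18) and the chemokine receptor gene Cxcr3 (0.92 ± 0.12), with a list median of 0.54 (camera, adjusted p = 1.2e-07; adjusted p = 0.239 with an estimated correlation). Tbx21, the lineage regulator of these cells, had a log2 fold change of -0.29 ± 0.20 (adjusted p = 0.401). Of 16 cytotoxic genes, Gzmb, Prf1 (perforin, 0.77 ± 0.12) and Nkg7 (0.53 ± 0.13) rose and Tnfsf10 (TRAIL) fell by 0.71 ± 0.13 on the log2 scale (6 and 1 adjusted over the list alone; camera, adjusted p = 6.9e-04; adjusted p = 0.239 with an estimated correlation). Under the replicate block 12 type 1 and 9 cytotoxic genes rose. Without dE2 replicate 2 the members that rose numbered 6 co-inhibitory, 4 type 1 and 1 cytotoxic. The Nkg7 call was lost without dE2 replicate 2 (adjusted p = 0.13), FL replicate 1 (0.13) or FL replicate 2 (0.085), and without the composition factor (0.053). Cd8a, chosen after its values were seen, was 99.2 CPM in dE2 replicate 1, 33.9 and 28.8 in dE2 replicates 2 and 3, and 32.7, 14.9 and 30 in FL. With dE2 replicate 1 left out, 10 co-inhibitory, 9 type 1 and 4 cytotoxic genes rose.

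**Figure D2:**
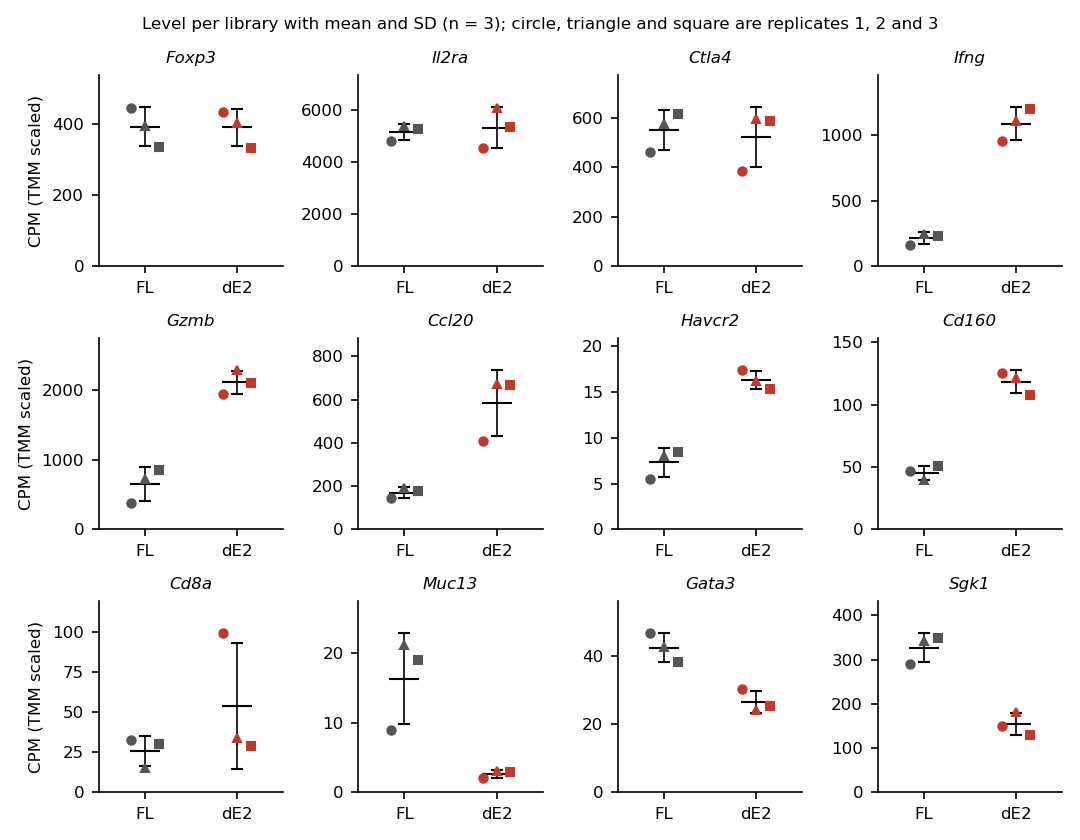
CPM after TMM scaling (vertical axes, from 0) for 12 genes in the 3 FL (grey) and 3 dE2 (red) libraries, with the mean and SD. Foxp3, Il2ra and Ctla4 overlap between groups, Ifng and Gzmb lie higher in all dE2 libraries, and dE2 replicate 1 has the highest Cd8a (99.2 CPM).

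Of 33 tested members of the Treg signature, 7 rose, 1 fell and 25 did not pass (10 and 1 adjusted over the list alone). The costimulatory receptor gene Tnfrsf9 (1.05 ± 0.13), Cd83 (1.13 ± 0.15), the inhibitory receptor gene Tigit (0.83 ± 0.14) and the cytokine gene Il10 (2.38 ± 0.39, from 0.758 to 3.90 CPM) rose, and Socs2 fell by 0.64 ± 0.12. Of these, Tigit is also a co-inhibitory gene and Tnfrsf9 an early T cell receptor gene. The list median was 0.22 (camera, adjusted p = 0.0058; adjusted p = 0.239 with an estimated correlation). Under the replicate block 14 members rose and 3 fell; 4 rose without FL replicate 2 or dE2 replicate 2, and 2 fell without dE2 replicate 1. Without the composition factor 4 members rose and the list median was 0.079. Of 14 follicular helper genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone), with Pdcd1, Cd200, Btla (0.92 ± 0.15) and Slamf1 (0.78 ± 0.14) as examples (camera, adjusted p = 8.2e-06; adjusted p = 0.239 with an estimated correlation). Pdcd1, Cd200 and Btla also stand in the co-inhibitory list, and the follicular regulator Bcl6 had a log2 fold change of 0.03 ± 0.22 (adjusted p = 0.96). Without dE2 replicate 2, 5 follicular helper genes rose.

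Genes of the type 2 and type 17 programmes were split. Of 14 type 2 genes, Il24 and the interleukin 33 receptor gene Il1rl1 (1.22 ± 0.20) rose and Gata3 fell (4 and 2 adjusted over the list alone; camera, adjusted p = 0.021; adjusted p = 0.239 with an estimated correlation). Without dE2 replicate 3 the camera result was an adjusted p of 0.066, and 4 type 2 genes rose without dE2 replicate 1. Ccr4 (0.37 ± 0.13, adjusted p = 0.089) passed with the replicate block (0.0020) and without dE2 replicate 1 (0.016), and Il4 did not pass at 1.47 ± 0.532 and 2.14 ± 0.486 CPM (adjusted p = 0.308). Of 14 type 17 genes, the chemokine gene Ccl20 rose and the interleukin 6 receptor gene Il6ra fell by 0.72 ± 0.14 (2 and 2 adjusted over the list alone; camera, adjusted p = 0.478). The Il6ra call was lost without dE2 replicate 2 (adjusted p = 0.080). Il17a (0.647 ± 0.735 and 0.762 ± 0.346 CPM, adjusted p = 0.859) did not pass. Under the block 7 type 2 genes rose and 2 fell, and 3 type 17 genes rose and 2 fell (fry, adjusted p = 0.012). Of the type 17 genes, 3 fell without FL replicate 2, and 2 without dE2 replicate 1, without the composition factor or with DESeq2.

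T cell receptor and cytokine signals showed changes in both directions. Of 27 early T cell receptor genes, Tnfrsf9, Egr2 (0.83 ± 0.13), the activation marker gene Cd69 (0.84 ± 0.17), Cd40lg and Zbtb32 rose and the phosphatase gene Dusp5 fell by 0.66 ± 0.13 (5 and 1 also adjusted over the list alone; camera, adjusted p = 0.0038; adjusted p = 0.773 with an estimated correlation). Il2 was 7.39, 23.9 and 9.91 CPM in FL and 27.5, 41.7 and 91.4 in dE2. Its log2 fold change of 1.95 ± 0.72 did not pass with edgeR's quasi-likelihood test (adjusted p = 0.223), its likelihood ratio test (0.063) or DESeq2 (0.050), and passed with limma-voom (0.020). That likelihood ratio test used filtered genes and robust dispersions. The authors' likelihood ratio test on all genes without the robust setting gave Il2 an adjusted p of 1.9e-04. Of 22 IL-2 and STAT5 targets, Prf1, Lta (0.72 ± 0.14), Gzmb and Cdk6 rose, and Socs2, Socs1, Socs3 and Ccnd3 fell (8 and 6 adjusted over the list alone; camera, adjusted p = 0.507). The 3 Socs genes, feedback inhibitors of cytokine receptors, had log2 fold changes of -0.64 ± 0.12, -0.77 ± 0.16 and -0.51 ± 0.13. Of 23 TGF-beta response genes, the co-receptor gene Tgfbr3 (1.12 ± 0.14), Cd83, Rgs16 (0.60 ± 0.12) and Serpine2 (0.75 ± 0.14) rose and Id1 fell (6 and 1 adjusted over the list alone; camera, adjusted p = 0.15). Of 20 naive and recirculation genes, Il7r (0.64 ± 0.12) and Ccr7 (0.59 ± 0.14) rose and Itga6, Satb1 and Foxo1 fell (2 and 5 adjusted over the list alone; camera, adjusted p = 0.237). Of 38 interferon response genes, Cxcl10 and Bst2 (0.43 ± 0.12) rose and Cmpk2 fell by 0.82 ± 0.20 (2 and 1 also adjusted over the list alone; camera, adjusted p = 0.258). Cd40lg, Zbtb32, Cdk6, Socs3, Ccnd3, Id1 and Foxo1 were chosen after their values were seen, and each lost its call without single libraries. Without dE2 replicate 2 the adjusted p of these 7 was 0.10, 0.17, 0.10, 0.18, 0.23, 0.19 and 0.15. Without FL replicate 1 it was 0.067 for Zbtb32, 0.15 for Cdk6, 0.16 for Socs3, 0.12 for Ccnd3, 0.16 for Id1 and 0.21 for Foxo1. Without FL replicate 2 it was 0.051 for Cdk6, 0.066 for Socs3, 0.13 for Ccnd3, 0.065 for Id1 and 0.061 for Foxo1, and without FL replicate 3 0.084 for Zbtb32, 0.067 for Cdk6, 0.11 for Ccnd3 and 0.074 for Id1. Leaving out dE2 replicate 3 gave 0.090 for Zbtb32, 0.053 for Ccnd3, 0.096 for Id1 and 0.061 for Foxo1.

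Under the replicate block, the members that rose and fell numbered 11 and 2 of the early T cell receptor genes, 8 and 6 of the STAT5 targets, 8 and 5 of the TGF-beta genes, 2 and 7 of the naive genes and 3 and 5 of the interferon genes. Leaving out dE2 replicate 2 ended the calls of Dusp5 (adjusted p = 0.055), Cd69 (0.084), Lta (0.059), Socs1 (0.072), Serpine2 (0.063), Ccr7 (0.12), Itga6 (0.12), Satb1 (0.15), Cmpk2 (0.12) and Bst2 (0.13). Without FL replicate 1 the calls of Socs1 (0.055), Itga6 (0.11), Satb1 (0.16), Cmpk2 (0.096) and Bst2 (0.21) were lost. The same held without FL replicate 2 for Ccr7 (0.086) and Bst2 (0.073), without FL replicate 3 for Itga6 (0.057), Satb1 (0.055) and Bst2 (0.095), and without dE2 replicate 3 for Cd69 (0.059), Satb1 (0.11) and Bst2 (0.064). Bst2 also lost its call without the composition factor (0.12), and Satb1 with limma-voom (0.050) and with the length trend removed (0.055). Without that factor 5 naive genes fell, and 1 interferon gene rose and 3 fell. With DESeq2 5 naive and 2 TGF-beta genes fell, and with limma-voom 1 naive gene, 2 STAT5 targets and 0 TGF-beta genes fell. As list counts, the early T cell receptor genes that rose numbered 2 without dE2 replicate 2 and 3 without dE2 replicate 3, and 3 fell without dE2 replicate 1. Of the STAT5 targets 1 rose and 1 fell without dE2 replicate 2, 1 fell without FL replicate 1 and 2 without FL replicate 2. Of the TGF-beta genes 4 fell without dE2 replicate 1 and 0 without any 1 of the other 5 libraries. Of the naive genes 0 fell without FL replicate 1 or dE2 replicate 2 and 1 without dE2 replicate 3, and 1 rose without FL replicate 2 or dE2 replicate 2. A single interferon gene rose without FL replicate 1, 2 or 3 or without dE2 replicate 2 or 3. Camera passed the TGF-beta genes, in the upward direction, without FL replicate 1 (adjusted p = 0.033). It passed the interferon genes, in the downward direction, without FL replicate 3 (0.047) or dE2 replicate 2 (0.034). With all libraries 8 of the 38 interferon genes had a positive log2 fold change, and the list median was -0.12.

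**Figure D3:**
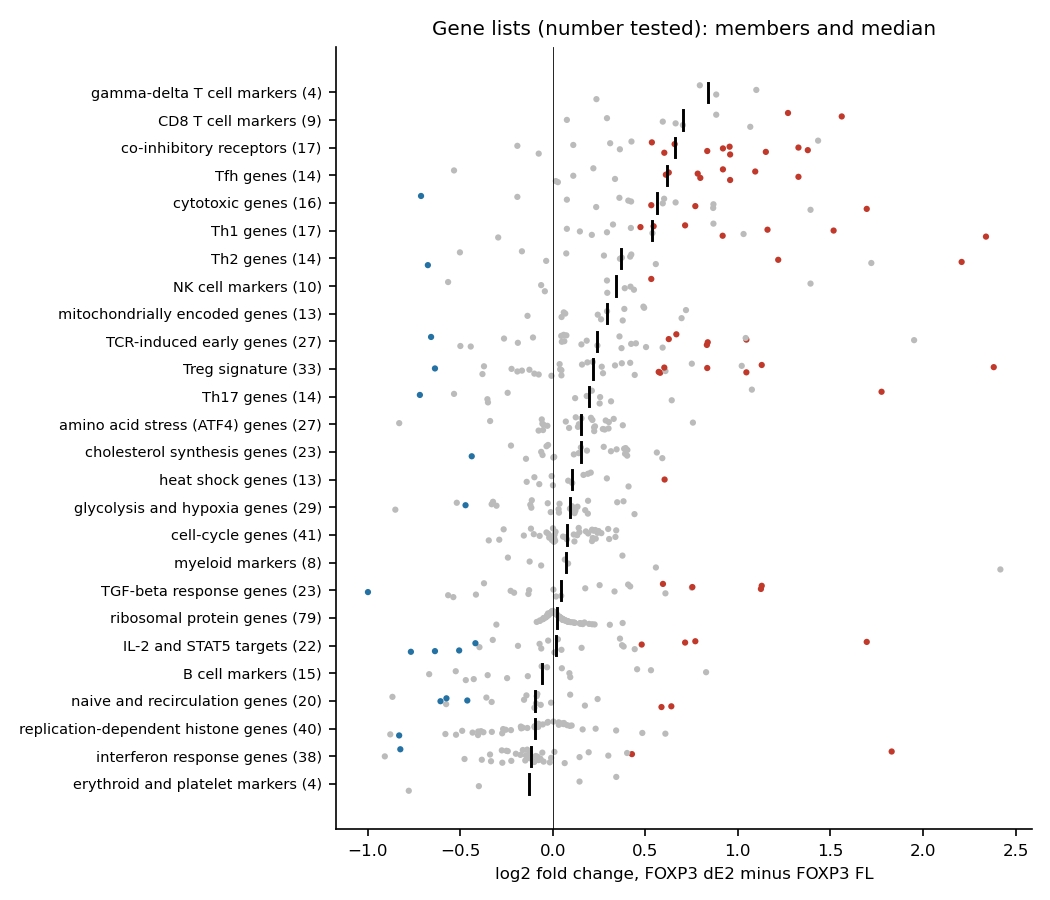
Log2 fold change (dE2 minus FL, horizontal axis) of the tested members of the 26 gene lists, with the number tested in parentheses and the list median as a black bar, 3 libraries per group. Red and blue points passed adjusted p under 0.05 and grey points did not; the co-inhibitory list has a median of 0.66 with 10 of 17 members higher.

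Cell cycle, metabolic and stress lists held few or no calls with edgeR's quasi-likelihood test. None of 41 cell-cycle genes passed with it, the likelihood ratio test, DESeq2 or limma-voom (4 higher and 2 lower at an unadjusted p under 0.05; camera, adjusted p = 0.15), with Ccna2 at -0.35 ± 0.12 and Cdc6 at 0.34 ± 0.13 (adjusted p = 0.092 and 0.113). Of 29 glycolysis and hypoxia genes Pdk1 alone fell, by 0.47 ± 0.14 (adjusted p = 0.048; camera for the list, adjusted p = 0.705), and over the list alone 0 passed. With DESeq2 2 glycolysis genes fell and with limma-voom 0, where Pdk1 had an adjusted p of 0.074. Of 23 cholesterol synthesis genes Mvd alone fell, by 0.44 ± 0.13 (1 and 1 adjusted over the list alone; camera, adjusted p = 0.064). With DESeq2 5 cholesterol genes rose and 1 fell, with the likelihood ratio test 1 and 1, and with limma-voom 0 and 0, where Mvd had an adjusted p of 0.055. Under the replicate block 10 cholesterol genes rose and 1 fell (camera, adjusted p = 0.0096), and 6 rose without dE2 replicate 1. Cyp51 (0.56 ± 0.18) had an adjusted p of 0.088 without and 1.6e-06 with the block, and 0.011 without dE2 replicate 1. Of 13 heat shock genes Hspd1 alone rose, by 0.60 ± 0.15 (1 and 0 adjusted over the list alone; camera, adjusted p = 0.15), and its reads overlap those of Hspe1 on the opposite strand. None of 27 ATF4 stress genes (camera, adjusted p = 0.125), 79 ribosomal protein genes (0.314) or 13 mitochondrially encoded genes passed with edgeR's quasi-likelihood test. At an unadjusted p under 0.05 they held 3, 1 and 6 higher and 1, 0 and 0 lower genes. With DESeq2, and also with the likelihood ratio test, 1, 0 and 1 higher and 1, 0 and 0 lower genes passed, and with limma-voom 0 did. The mitochondrial list had a median of 0.29, with mt-Cytb at 0.39 ± 0.16 (camera, adjusted p = 0.0055; adjusted p = 0.756 with an estimated correlation), and without FL replicate 2 camera gave an adjusted p of 0.076. Its median was 0.15 without the composition factor. In the authors' mapping table mitochondrial reads were 2.64%, 1.82% and 1.91% in FL replicates 1 to 3 and 2.07%, 2.08% and 2.23% in dE2 replicates 1 to 3. Of 40 histone genes H1f0 alone fell, by 0.83 ± 0.18 (0 and 1 adjusted over the list alone; camera, adjusted p = 0.213). The calls of Pdk1, Mvd, Hspd1 and H1f0 were lost without dE2 replicate 2, at adjusted p = 0.24, 0.082, 0.19 and 0.14, and without FL replicate 2, at 0.20, 0.17, 0.11 and 0.080. Pdk1 was also lost without FL replicate 3 (0.11) or dE2 replicate 1 (0.12), Mvd without FL replicate 1 (0.11), FL replicate 3 (0.082) or dE2 replicate 3 (0.078), Hspd1 without FL replicate 3 (0.057) and H1f0 without dE2 replicate 3 (0.054). The Mvd call was lost with the GC trend removed (0.20) and the Pdk1 call with the length trend removed (0.063) and with CPM of at least 5 in 3 libraries (0.051). Without the composition factor 1 cell-cycle, 2 glycolysis, 1 ATF4 and 2 histone genes fell. In the camera results that follow, the histone genes went down and the other lists went up. Camera passed cell-cycle (adjusted p = 0.0023) and ribosomal genes (0.0031) without dE2 replicate 3, glycolysis (0.0081), heat shock (0.036) and cholesterol genes (0.0018) without FL replicate 2, ATF4 genes without FL replicate 2 (0.042), FL replicate 3 (0.043) or dE2 replicate 2 (0.026), cholesterol genes also without FL replicate 3 (0.035) or dE2 replicate 1 (0.0087), and histone genes without FL replicate 1 (0.038) or dE2 replicate 1 (0.027). Without 1 library, 2 glycolysis genes fell (FL replicate 1 or dE2 replicate 3), 2 and 3 histone genes fell (FL replicate 3 and dE2 replicate 1), and 2 cell-cycle genes fell (dE2 replicate 1) or rose (dE2 replicate 3). Under the block 5 cell-cycle genes rose and 3 fell, 3 glycolysis genes rose and 4 fell, 3 ATF4 genes rose and 1 fell, 3 heat shock and 8 mitochondrial genes rose, 1 ribosomal gene rose and 1 fell, and 3 histone genes fell.

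Markers of other cell types were measured in the same libraries. Of 9 CD8 T cell markers, all with a positive log2 fold change, the chemokine gene Xcl1 (1.27 ± 0.15, 562 to 1360 CPM) and Crtam (1.56 ± 0.16) rose (5 and 0 adjusted over the list alone; camera, adjusted p = 1.5e-04; adjusted p = 0.239 with an estimated correlation). Cd8b1 was 17.5 ± 3.19 CPM in FL and 28.5 ± 9.15 in dE2 (adjusted p = 0.090, 4.3e-06 with the replicate block, where 5 of the 9 rose, and 0.049 without dE2 replicate 3). With DESeq2 5 CD8 markers rose and with the likelihood ratio test 4. Of 10 NK cell markers Nkg7 alone rose (1 and 0 adjusted over the list alone; camera, adjusted p = 0.15, and 0.043 and 0.017 without FL replicate 3 and dE2 replicate 2; 0 rose without the composition factor), and Gzma was 105 CPM in dE2 replicate 1 against 26.8 and 29.9 in the other dE2 libraries. None of 4 gamma-delta T cell markers passed the quasi-likelihood test over all genes, and 3 rose adjusted over the list alone and with the replicate block (camera, adjusted p = 0.017; adjusted p = 0.698 with an estimated correlation), with Tcrg-C2 going from 112 ± 40 to 241 ± 58.1 CPM. Those 3 were the gamma chain genes Tcrg-C1, Tcrg-C2 and Tcrg-C4. The delta chain gene Trdc was 3.97 ± 1.48 CPM in FL and 4.63 ± 1.64 in dE2 (adjusted p = 0.705, and 0.475 with the replicate block). Camera gave gamma-delta markers an adjusted p of 0.064 without FL replicate 2 and 0.091 without dE2 replicate 1, and 3 of them rose without FL replicate 1. At an unadjusted p under 0.05 they held 3 higher genes, and 3 passed with DESeq2, 3 with the likelihood ratio test and 2 with limma-voom. None of 15 B cell, 8 myeloid or 4 erythroid and platelet markers passed that test (camera, adjusted p = 0.653, 0.343 and 0.692), with 4, 1 and 0 at an unadjusted p under 0.05 and 1, 0 and 0 with DESeq2 or the likelihood ratio test, and 0 with limma-voom. Without the composition factor 1 B cell marker fell. Under the block 1 B cell marker rose and 2 fell and 1 myeloid marker rose. Among them Cd74 was 342 ± 68.3 CPM in FL and 469 ± 41.9 in dE2 (adjusted p = 0.062, 7.2e-05 with the replicate block, 0.040 without FL replicate 3 and 0.031 without dE2 replicate 1), Lyz2 was 1.14 ± 0.847 and 5.91 ± 7.61, and Hba-a1 was 1.15 ± 0.753 and 0.666 ± 0.0946. With the block, camera kept each of the list calls given above. Fry, which asks whether a list's genes move one way on balance, passed none of those lists with the block (adjusted p from 0.0639 to 0.451). Without the block, fry passed the Treg, follicular helper and co-inhibitory lists (adjusted p = 0.021 each), the type 1 and CD8 lists (0.027 each) and the type 2 list (0.0496). It did not pass the early T cell receptor, cytotoxic, gamma-delta or mitochondrial lists.

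The authors' deposited table holds their own edgeR calls on the same counts. It lists 726 genes as higher and 482 as lower in dE2 at an adjusted p under 0.05. All 548 and 355 genes called here are among them in the same direction, 0 have the opposite direction, and 178 and 127 are in the authors' deposited table only. Il2 is one of these, with an adjusted p of 1.9e-04 in the authors' deposited table. At more than 1.5-fold the authors' deposited table gives 342 and 274 genes, of which 269 and 196 were called here. Its enrichment sheets list 665 of 1377 terms for the higher and 30 of 339 for the lower genes at an adjusted p under 0.05. In the authors' deposited table, cytokine-cytokine receptor interaction has 32 of the higher genes (8.03-fold, adjusted p = 2.0e-19) and endoplasmic reticulum lumen has 13 (6.61-fold, adjusted p = 6.4e-06). Wnt signaling has 13 of the lower genes there (2.98-fold, adjusted p = 0.025).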

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

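The replicate block gave 1678 higher and 1471 lower genes (99 lower by at least 2-fold), or 1827 and 1366 (97) with the GC trend removed and 1763 and 1285 (96) with the length trend removed; all 548 and 355 genes kept their call with the block. No composition factor gave 264 and 954 (107 by at least 2-fold), limma-voom 227 lower, adjusted p under 0.01 184 and 57 (16), and glmTreat 33 and 6 genes. Lower genes by at least 2-fold numbered 30 with DESeq2 and 19 with CPM of at least 5 in 3 libraries, with fewer genes tested. With 1 library left out, higher genes ranged from 125 to 780 and lower genes from 51 to 587 (13 to 99 by at least 2-fold). DESeq2 size factors, upper quartile, the likelihood ratio test and no filter stayed within 1.5 times of both counts, and no setting turned a called gene. Of 122 named genes the block brought 38 from not passing to passing and ended no call, and it changed no call of a list with camera apart from the cholesterol genes. Of the calls shared with the authors' deposited table, 184 and 57 remained at adjusted p under 0.01, and 269 and 196 lie on the authors' 1.5-fold lists. Planned settings for a table without counts did not apply.

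No named gene that passed reversed. Foxp3 crossed 0 with the GC trend removed (0.03, also with the block), with the length trend removed (0.0026, and 0.0041 with the block) and within -0.11 to 0.094 with 1 library left out. Without the composition factor Il2ra was -0.091 and Bcl6 -0.10, and Bcl6 was -0.0035 with upper quartile scaling. Leaving out 1 library gave -0.063 to 0.15 for Il2ra, -0.19 to 0.10 for Ctla4, -0.22 to 1.76 for Il17a, -0.43 to 0.011 for Tbx21, -0.13 to 0.35 for Bcl6, -0.15 to 0.58 for Epor and -0.092 to 0.42 for Trdc.

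List values are adjusted p. An estimated correlation gave 0.239 for the Treg, Th1, Th2, Tfh, cytotoxic, co-inhibitory and CD8 lists, 0.773 for early T cell receptor, 0.698 for gamma-delta and 0.756 for mitochondrial genes; with the block (chosen after seeing the data) these were 0.605, 0.749, 0.665 and 0.749. Fry gave 0.333 for early T cell receptor and mitochondrial genes, 0.056 for cytotoxic and 0.320 for gamma-delta genes. The Treg, Tfh, co-inhibitory, Th1, CD8 and Th2 lists kept their calls with it (0.021 to 0.0496). Fry with the block gave 0.0892 for Treg, Tfh, co-inhibitory and CD8, 0.0639 for Th1 and Th2, 0.280, 0.152, 0.266 and 0.451 for early T cell receptor, cytotoxic, gamma-delta and mitochondrial lists, and 0.0123 for Th17. Fry without the composition factor (chosen after seeing the data) gave 0.293 for Treg, 0.122 for Th1, 0.384 for Th2 and gamma-delta, 0.672 for early T cell receptor, 0.253 for cytotoxic, 0.106 for CD8 and 0.670 for mitochondrial genes, and opposite directions for STAT5 and cell-cycle (0.672), glycolysis (0.827), ATF4 and heat shock (0.999) and ribosomal genes (0.670). Camera without that factor passed cholesterol (0.042) and NK (0.030) genes and turned B cell (0.867) and ribosomal (0.771) genes; camera with the block passed cholesterol genes (0.0096). With 1 library left out, camera ranged from 0.0044 to 0.066 for Th2, 3.9e-04 to 0.091 for gamma-delta, 4.8e-07 to 0.076 for mitochondrial, 0.069 to 0.939 for B cell, 0.017 to 0.834 for NK, 0.033 to 0.689 for TGF-beta, 0.026 to 0.526 for ATF4, 0.0023 to 0.605 for cell-cycle, 0.0018 to 0.683 for cholesterol, 0.468 to 0.985 for erythroid, 0.0081 to 0.932 for glycolysis, 0.036 to 0.484 for heat shock, 0.034 to 0.932 for interferon, 0.027 to 0.925 for histone and 0.0031 to 0.738 for ribosomal genes. Counts of 0 in a list became 1 for lower follicular helper genes without FL replicate 2 or dE2 replicate 1, higher mitochondrial genes without FL replicate 1, higher and lower ATF4 genes without FL replicate 2 and dE2 replicate 1, higher B cell genes without FL replicate 3 or dE2 replicate 1 and lower ones without dE2 replicate 3, higher glycolysis and lower ribosomal genes without dE2 replicate 1, and higher gamma-delta genes without dE2 replicate 3. The cause of these changes was not tested.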

Other observations

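Chosen only after the results were seen were the 4 gene families, the test on CD8 T cells, and, for GC content and gene length, the use of the fit with the replicate block and of an interval's lower limit as the deciding test, although the limits of 50% and 80% had been set before. Ligands of the TNF family may rise as a group in dE2: of 13 tested, 8 rose (Tnfsf8 by a log2 fold change of 1.55, Cd70 1.82, Tnfsf14 1.25, Tnfsf4 1.08, and Lta, Tnfsf9, Cd40lg and Tnf) and Tnfsf10 fell (median 0.72; camera, p = 2.6e-07; p = 0.038 with an estimated correlation), and 4 rose without dE2 replicate 2. Chemokine ligands may too: of 12 tested, 7 rose (Ccl20, Ccl1, Ccl3, Xcl1, Cxcl10, Ccl4 and Ccl9) and 0 fell (median 1.04; camera, p = 4.5e-08; p = 0.019 with an estimated correlation). Of 23 genes of the ER translocon, signal peptidase and oligosaccharyltransferase, which move proteins into the secretory path and glycosylate them, 7 rose (Stt3a by 0.80, Sec61a1 by 0.76, Rpn2, Ssr3, Dad1, Ssr2 and Rpn1) and 0 fell (median 0.35; camera, p = 1.6e-07; p = 0.116 with an estimated correlation). Those that rose numbered 0 without dE2 replicate 2, 2 without FL replicate 1 or FL replicate 2, 4 without FL replicate 3 and 11 without dE2 replicate 1, and 14 with the block, 4 without the composition factor and 11 with DESeq2. The membership first written down had also the symbols that begin with Srp, and not Sec11a and Sec11c; with it 9 of 34 genes rose and 0 fell (median 0.28; camera, p = 3.6e-08; p = 0.069 with an estimated correlation), so the group stayed past camera and short of an estimated correlation either way. Adjusted over the 4 families tested, of which these 3 are reported, p with an estimated correlation was 0.060, 0.060 and 0.116, so none of the 3 held there, and each is a hypothesis from the same data.

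The 548 higher and 355 lower genes were set against other splits of the 6 libraries. The 10 splits into 3 and 3 are too few for a share under 0.05. The real split was the 1 that gave as many genes in one direction (548, or 355 lower), and the highest other gave 13. Every other split puts both genotypes in each group. A genotype difference then adds to the spread within groups and lowers the counts, so these counts do not show what chance alone would give. The 3 other splits that part all 3 pairs gave 0 genes each, with and without the replicate block. Tables argue against a GC content or gene length trend as the whole cause. With the block, 96.7% of the higher and 85.5% of the lower calls kept their call and direction once the GC trend was removed, and 98.6% and 87.2% once the length trend was. These shares were first computed without the block, where 93.8% and 96.2% of the higher calls and 81.7% (Wilson 95% interval 77.3% to 85.4%) and 80.3% (75.8% to 84.1%) of the lower calls kept theirs. The intervals for lower genes span the limit of 80%, so part of the lower calls may rest on such trends. A genotype effect stays open as the untested biological explanation.

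Part of the effector and co-inhibitory genes were higher in dE2, and 1 candidate explanation is that the dE2 cultures held more CD8 T cells, although the cells were made from naive CD4 T cells. Cd8a and Cd8b1 were highest in dE2 replicate 1. Without that library, the 20 members of the type 1, cytotoxic and co-inhibitory lists that had passed with all libraries had a median log2 fold change of 0.95, and all 48 tested members, passing or not, had 0.53. Cd8a then stood at 0.28 (95% interval -0.72 to 1.28) and Cd8b1 at 0.41 (0.07 to 0.75). The 20 members were picked as passing, which raises their median, and the median of all 48 lay below the upper limits of both genes. More CD8 T cells thus cannot be told apart from a change within CD4 T cells, because the 2 genes varied too much over few libraries. Of the 9 tested CD8 markers, Xcl1, Crtam and Ccl5 are also made by activated CD4 T cells.

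Without a composition factor the median gene was lower in dE2 by a log2 fold change of -0.14. Leaving the 50 most abundant genes out of the library totals moved this to -0.12, so a larger share taken by those 50 genes was not enough to explain it. Those genes took 14.6% to 15.2% of the reads in FL and 15.6% to 16.3% in dE2. With 2000 genes left out the median was -0.03, so the gain in dE2 was spread over many abundant genes, and it could be technical or biological. Ccl4, Gzmb and Lta gained most, by 0.145, 0.133 and 0.128 percentage points.

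Within 1 Mb of Foxp3, 2 of 30 tested genes were called (Praf2 and Clcn5, both higher and chosen after their values were seen), 6.67% against 6.17% of other genes (Fisher's exact test, two-sided, p = 0.708). Calls near the edited locus were thus neither absent nor more frequent beyond counting error.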
